A study of Mus musculus with 9 samples.

How the data were processed

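RNA from 9 constructs was profiled by 3' end sequencing. Per the labels' protocols, C2C12 myoblasts in muscle-derived matrix were kept for 2 days in growth medium and 10 days in medium with 10% equine serum. Libraries were made from 100 ng of total RNA with the QuantSeq 3' mRNA FWD kit, which primes first-strand synthesis with oligo-dT and second-strand synthesis at random, and were read as single-end 75 bp reads on a NextSeq 550. The labels state no molecular identifiers. Per the submitters' processing notes, FastQC, STAR and HTSeq and the builds GRCm39 and mm39 were named, without versions or roles. The annotation, the strand setting and the treatment of duplicates are not given in the sources used here, so overlapping genes, antisense partners and near-identical copies may share reads.

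The deposited values are whole-number counts per gene symbol, 1 column for each library, not normalized, per the file headers and the values themselves. Each of the 9 files lists 40879 symbols, of which 18619 had a count in any library. The number in each column name is 1 above the number in the label in all 9 files, and samples were taken from the series' own record of which file belongs to which sample. No coordinates are given, because the reference annotation at hand is of another build, and gene names are those of the files.

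Samples were grouped by their titles into normal, irradiated and cocultured. The titles call the replicates biological, while the series design text has 2 constructs of a condition in each dish, so replicates may share a dish and p-values measure the spread between these samples. A cocultured construct, however, shared its dish with an irradiated one, so libraries of these groups may also be dish partners. The labels name no such pairs, and the main model holds no pairing. Before replicates were averaged they were compared pairwise. Within-group pairs differed far beyond counting noise (chi-square per gene 39.0 to 325) and had Spearman correlations across genes of 0.63 to 0.84, and none was treated as a duplicate. Replicate numbers are shared between groups, and whether they pair samples was checked as reported with the other processing choices.

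Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. filterByExpr at its defaults kept 11980 genes, TMM factors were computed, and 1 quasi-likelihood model (glmQLFit, glmQLFTest) with group as its term was fitted to all 9 libraries, so that the groups share an estimate of spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Normalised CPM use TMM-scaled library sizes. Standard errors are the log2 fold change divided by the square root of F and are approximate. The square root of the common dispersion was 1.32. For a gene without counts in a whole group, a bound was computed against a floor of 3 counts over the group, and ratios of genes with few counts carry an exact binomial counting interval. Floors and intervals cover counting error only and take reads as independent.

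The 39 gene lists were fixed before the data were examined. They cover p53 targets, senescence markers, SASP factors, NF-kB and interferon genes, cell cycle, replication and repair, 6 classes of matrix genes and TGF-beta response, adhesion, myogenesis, fusion and sarcomeres, calcium handling, atrophy, energy metabolism, lysosome, stress responses, lipid synthesis, complement, ribosomal proteins, immediate early genes, nuclear RNAs and markers of 6 other cell types. Of 1177 entries 1168 matched a symbol. Lists were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), with camera at an estimated correlation, and with fry, which tests whether members move on balance one way and does not compare a list with other genes. Each list's members were also adjusted over the list alone.

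Genes were named by a rule fixed at the same time: in each comparison against normal up to 6 called genes per direction with at least 10 CPM on average, no overlap between groups and no predicted or pseudogene symbol, a panel of 10 genes whatever their result, up to 4 members of each called list with the smallest adjusted p, and up to 2 passing members of other lists. In the direct comparison of irradiated and cocultured constructs 5 per direction and the panel were named. Genes named outside the rule are said to be so. A gene that the rule names is not reported here.

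The test was checked on simulated data drawn from the real means, library sizes and dispersions with 200 changed genes among 11980. For irradiated against normal constructs at the estimated dispersion it recovered 0% of 50 genes changed 2-fold, 8% at 4-fold, 6% at 8-fold and 16% at 16-fold, with 2 false calls. At a low dispersion it recovered 52%, 98%, 100% and 100%, with 11 false calls. Alternatives covered DESeq2 1.42.0, limma voom, other scalings and filters, the 6 libraries of a comparison alone, a replicate block, each library left out, mitochondrial genes removed and other thresholds. A mean of at least 50 CPM, omission of normal 3 and irradiated 1, and voom with library weights were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.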

Results

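Gene expression was measured in engineered 3D skeletal muscle made from C2C12 cells, a mouse myoblast line that fuses into myotubes when growth serum is withdrawn, embedded in matrix prepared from muscle tissue. The 9 libraries fall into 3 groups of 3. Normal constructs were not irradiated, irradiated constructs received a single X-ray dose of 20 Gy to induce senescence, and cocultured constructs were not irradiated but shared a dish with an irradiated one. The series design text counts 2 samples each for the irradiated and normal conditions, while the labels describe 3 libraries each, and all 3 were used. Library totals ranged from 4840993 to 6607557 counts in normal, from 6485655 to 8290468 in irradiated and from 7506605 to 8035763 in cocultured constructs. Between 8306 and 14159 genes were detected per library, with the fewest in irradiated 2 (8306) and irradiated 3 (8654).

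The libraries differed in composition within groups as well as between them. Members of the adult and mature sarcomere list, the contractile genes of grown muscle fibres, took 17.1% of the counts of normal 3 (exact 95% interval 17.1% to 17.2%) and 13.4% of irradiated 1 (13.4% to 13.4%), against 1.17% to 3.14% in the other libraries. Mitochondrially encoded genes took 29.7% of normal 3 and 21.6% of irradiated 1, and 5.76% to 13.4% elsewhere. Gm26917, a predicted gene singled out after its values were seen, took 20.2 ± 9.49% of counts in normal, 7.35 ± 4.05% in irradiated and 3.61 ± 0.274% in cocultured constructs (SD, n = 3 each). By library it took 9.47% to 27.4% in normal constructs, a range that held irradiated 1. Irradiated 2 (4.76%) and irradiated 3 (5.28%) lay nearer to the cocultured libraries (3.38% to 3.91%). TMM factors split alike, at 0.556 to 0.973 in normal libraries and irradiated 1 and 1.18 to 1.29 in the others. Whether these sets differ in preparation was not tested. The first set holds all normal and no cocultured libraries, so such a difference could not be told from coculture. Of genes with 20 to 50 CPM on average in the normal and cocultured libraries, 20.8% had no count in irradiated 2 and 17.3% in irradiated 3, compared with 0.101% to 5.50% in the other 7 libraries. On the first principal component (25.8% of variance) irradiated 1 lay at -32.2, nearer to the normal (-90.2 to -72.7) and cocultured libraries (-50.2 to -4.85) than to irradiated 2 (224) and irradiated 3 (162). The exact intervals treat each read as independent. PCR copies are not independent molecules, so these intervals may be too narrow even for counting error.

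**Figure D1:**
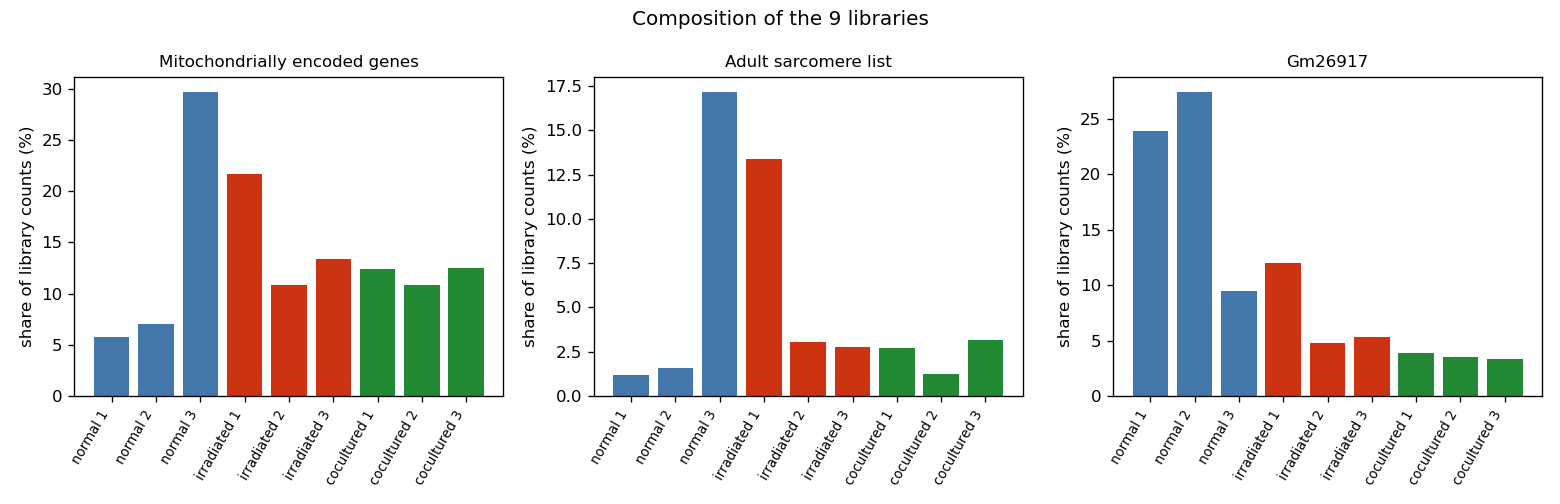
Share of each library's counts, in percent, taken by mitochondrially encoded genes, by the adult sarcomere list and by Gm26917, with a bar per library coloured by group. Normal 3 and irradiated 1 stand above the other libraries in the first and second panels, at 29.7% and 21.6% and at 17.1% and 13.4%.

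The first comparison asked which transcripts differ between irradiated, senescence-induced constructs and normal ones. Fbln7, which encodes a secreted matrix protein of the fibulin family, rose from 10.7 ± 7.45 to 334 ± 123 normalised CPM (SD, n = 3 each), a log2 fold change of 4.97 ± 0.60 (SE), and of 5.68 without normal 3. Col12a1, a collagen that associates with collagen fibrils, fell from 806 ± 259 to 53.4 ± 31.4 CPM (log2 -3.92 ± 0.49, and -4.51 without irradiated 1). Inhba, the subunit of activin A, fell from 459 ± 224 to 40.9 ± 2.87 CPM (log2 -3.49 ± 0.43). Nt5e, the cell-surface enzyme that makes adenosine from AMP, averaged 128 ± 45.6 CPM in normal constructs and had no count in any irradiated library, which makes it at least 1020-fold lower against a floor of 3 counts over the group. Rrp1b and Gap43, a growth-associated protein of neurons, were also without counts in the 3 irradiated libraries, and were at least 494-fold and at least 405-fold lower. These bounds cover counting error only. Irradiated 2 and irradiated 3 lacked counts for 20.8% and 17.3% of the genes with 20 to 50 CPM elsewhere, so smaller changes are possible.

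These genes and Wfdc17 were the 7 called among 11980 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1 higher and 6 lower in irradiated constructs. Their adjusted p-values ran from 2.94e-04 for Nt5e, through 0.00512 for Fbln7, Rrp1b, Col12a1 and Inhba and 0.00892 for Gap43, to 0.0354 for Wfdc17. Wfdc17 had 1332 counts over the normal and 4 over the irradiated libraries, a ratio of 615 with a counting interval of 239 to 2259. In all 7 the 3 libraries of the irradiated group lay apart from the 3 of the normal group, as they did in 15.7% of all tested genes, against 10% by chance. At an unadjusted p under 0.05 there were 1232 genes, 190 higher and 1042 lower, where 599 would be expected by chance, and 680 of the lower ones had no count in a whole group.

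A fit of the 6 libraries compared called 0 genes, with adjusted p-values from 0.140 to 0.337 for these 7, while limma voom called 25 and DESeq2 667. The 25 held 5 of the 7, without Fbln7 (limma voom adjusted p = 0.147) and Wfdc17 (0.168). The count was 147 without irradiated 1, 14 without normal 2, 13 without irradiated 2, 17 without irradiated 3, and 20 without both normal 3 and irradiated 1, where 5 of the 7 were called. Inhba (edgeR adjusted p = 0.0676) and Wfdc17 (0.136) were not called there. Wfdc17 had an edgeR adjusted p of 0.120 without normal 1, 0.165 without normal 3 and 0.0530 without irradiated 2.

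**Figure D2:**
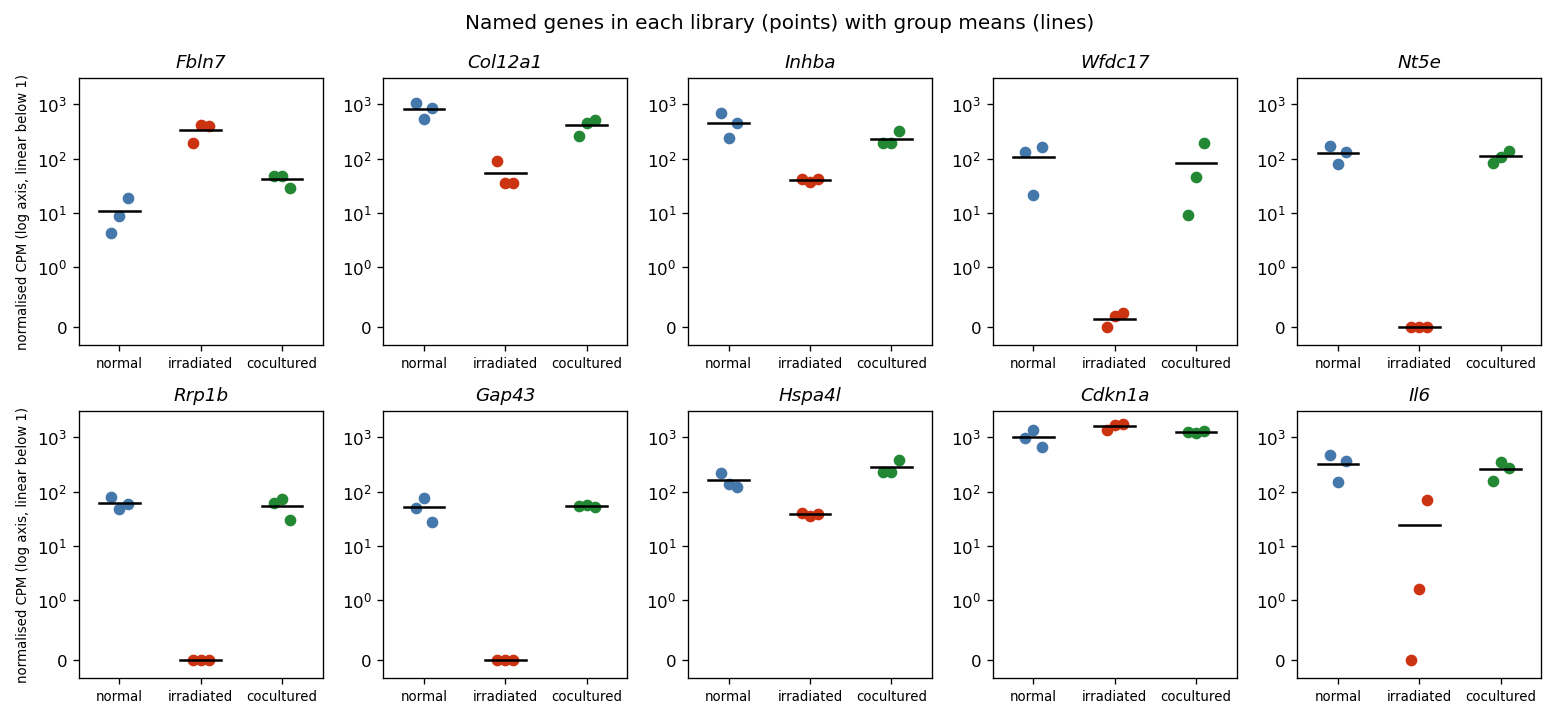
Normalised CPM of 10 genes in each of the 9 libraries (points, grouped on the horizontal axis, log vertical axis that is linear below 1) with group means as lines. Nt5e, Rrp1b and Gap43 lie at 0 in the 3 irradiated libraries, while Inhba lies between 37.6 and 42.6 CPM there.

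Genes of cell division showed the lowest values of any list. Of 32 tested members of the cell cycle and mitosis list, 31 had negative log2 fold changes, with a median of -4.13 that is unchanged when genes without counts are set to their bound. The median was -3.33 without normal 2, -4.73 without normal 3 and -8.01, -7.82 and -5.08 without irradiated 1, 2 or 3, fitted values that are no bounds. No member passed over all genes in edgeR with group as the only term, and 7 fell when adjusted over the list alone. Top2a, the topoisomerase of dividing cells, went from 137 ± 72.2 to 18.2 ± 10.2 CPM (SD, n = 3 each; log2 -2.91 ± 0.61), and it passed over all genes with DESeq2. Kif11, a spindle motor, Anln and Ttk had no count in any irradiated library and were at least 120-fold, 114-fold and 139-fold lower, for counting error only. 11 members had no count in a whole group, irradiated 2 and irradiated 3 being the libraries with the most genes of 20 to 50 CPM elsewhere at 0. The list was called lower by camera, a test of a list against all other genes, with an adjusted p of 1.08e-07 at a preset correlation of 0.01, and an adjusted p = 0.510 with an estimated correlation. In the fixed panel, Mki67 averaged 1.99 CPM in irradiated and 29.6 in normal constructs (log2 -3.93 ± 1.74, edgeR adjusted p = 0.483) and Lmnb1, a nuclear lamin, 4.33 and 27.3 CPM (log2 -2.67 ± 1.82, edgeR adjusted p = 0.826), so neither passed. Irradiated 1 held all their irradiated counts, 28 and 61, and without it both were called lower (edgeR adjusted p = 0.0190 and 0.0276), while without normal 2 their log2 values were -3.29 and -1.46. Leaving out irradiated 1 removes every irradiated count of both genes, so these calls add no support for a fall.

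Targets of p53 were called higher as a list by camera (33 tested, 23 positive, median log2 0.28, adjusted p = 0.0365), with an adjusted p = 0.394 with an estimated correlation. The call was lost without normal 2 (camera adjusted p = 0.0860), normal 3 (0.0543), irradiated 2 (0.185), irradiated 3 (0.145) or cocultured 1 (0.0507). It was also lost at a mean of at least 50 CPM (0.0818). None of its members passed the test, over all genes or adjusted over the list alone. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, averaged 1615 ± 196 CPM in irradiated and 996 ± 356 in normal constructs (log2 0.70 ± 0.33, edgeR adjusted p = 0.486). Ephx1 averaged 169 and 74.8 CPM, Zmat3 61.6 and 20.4 (log2 1.60, and 0.55 without irradiated 2, which held 125 CPM), and Pmaip1, a BH3-only gene of apoptosis, 0 and 12.6. Mdm2, the ubiquitin ligase of p53, differed by a log2 of 0.04 ± 0.50, and leaving out normal 1, irradiated 1 or irradiated 2 turned its sign, to -0.20, -0.01 and -0.08. Cdkn2a, the p16 locus, had no count in any of the 9 libraries and was not tested.

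Secreted inflammatory genes went both ways. Among 30 tested members of the SASP list, the cytokines and chemokines that senescent cells are known to secrete, 10 fell and 2 rose when adjusted over the list alone, and 1, Inhba, passed over all genes. Inhba did not pass over all genes without both normal 3 and irradiated 1 (log2 -3.52, edgeR adjusted p = 0.0676). The list as a whole was not called by camera (adjusted p = 0.433), while fry, which compares it with no other genes, called it lower (adjusted p = 0.0418). Il1a fell from 101 ± 56.1 to 0.852 ± 1.48 CPM, and irradiated 1 held all of its irradiated counts. Without that library Il1a passed over all genes (edgeR adjusted p = 0.00122), but no irradiated count is then left, so this adds no support. Il6 averaged 327 ± 163 CPM in normal and 24.1 ± 40.3 in irradiated constructs (log2 -3.76 ± 1.33), with an adjusted p of 0.483 over all genes and 0.0399 adjusted over the list alone in edgeR. Irradiated 3 held 602 of its irradiated counts and the other 2 held 0 and 17, and without irradiated 3 it was called lower over all genes (log2 -8.42, edgeR adjusted p = 0.00289). That omission removes most of the irradiated Il6 counts, so the call adds no support either. The 2 that rose, chosen for mention after their values were seen, were Cxcl12 (163 to 951 CPM, log2 2.54 ± 0.57) and Hgf (318 to 728 CPM, log2 1.20 ± 0.33). Ccl2 did not pass (33.2 and 59.9 CPM, log2 0.85 ± 1.24), and leaving out irradiated 3 turned its sign, to -2.82. Of 24 NF-kB targets, 6 fell and 2 rose adjusted over the list alone, with Ptgs2, the inducible cyclooxygenase, at 662 ± 536 and 2.56 ± 4.43 CPM and Ier3 at 660 ± 162 and 184 ± 47.3 CPM in normal and irradiated constructs. Ptgs2 passed over all genes without irradiated 1, the library that held all of its irradiated counts (edgeR adjusted p = 8.52e-04). This call too rests on the removal of those counts.

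The complement and acute phase list was called higher (23 tested, adjusted p = 0.0113 in camera, adjusted p = 0.394 with an estimated correlation), with a median log2 of 0.70 but a mean of -0.08. Adjusted over the list alone, 3 members rose and 5 fell. C3, the central complement component, went from 470 ± 56.4 to 1601 ± 291 CPM (log2 1.77 ± 0.35) and Apoe from 283 ± 130 to 894 ± 63.9 CPM (log2 1.66 ± 0.36), C3 passing over all genes without irradiated 1 (edgeR adjusted p = 0.0310), while the complement inhibitor Serping1 went from 1056 ± 355 to 239 ± 93.4 CPM (log2 -2.15 ± 0.43) and Lcn2 from 174 ± 134 to 22.5 ± 3.93 CPM (log2 -2.95, and -2.09 without normal 1). The lysosome and autophagy list was called higher (33 tested, 24 positive, median log2 0.36, camera adjusted p = 8.13e-04) with no member passing over all genes or adjusted over the list alone, and an adjusted p = 0.394 with an estimated correlation. Camera compares a list with all other genes, and the 2995 of lowest abundance had a median log2 of -1.31. At a mean of at least 50 CPM the lysosome and complement calls were lost (camera adjusted p = 0.282 and 0.588). Npc2 averaged 1329 CPM in irradiated and 839 in normal constructs, and the protease cathepsin B, Ctsb, 542 and 324 CPM.

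Matrix genes moved in both directions. Of 19 tested interstitial collagens, 3 rose and 3 fell adjusted over the list alone, among them Col6a1 (120 ± 38.6 to 473 ± 135 CPM, log2 1.98 ± 0.38) and Col12a1 above. Without irradiated 1, Col6a1 passed over all genes (edgeR adjusted p = 0.0190), as did the syndecan Sdc4 (0.0217). Of 16 basement membrane genes, Col4a1 rose (log2 1.27 ± 0.36) and Lama4 was 1 of 2 that fell (log2 -1.73 ± 0.38). Of 39 matrix glycoprotein genes 3 fell, including Igfbp2 (334 ± 40.9 to 12.2 ± 11.7 CPM, passing over all genes without irradiated 1 or irradiated 3, at edgeR adjusted p = 0.0498 and 0.00194) and Ccn2 (178 ± 65.9 to 47.5 ± 27.7 CPM), and of 22 proteoglycan genes 2 fell, Sdc4 and Prg4 (log2 -3.59, and -4.62 without irradiated 1). Pcolce, which enhances procollagen processing, was the 1 of 25 crosslinking genes that rose (log2 1.46 ± 0.35). None of these lists was called by camera, and fry called the basement membrane list lower (adjusted p = 0.0183, median log2 -0.01). Col1a1, the main fibrillar collagen chain, averaged 272 ± 253 and 275 ± 272 CPM in irradiated and normal constructs (log2 -0.01 ± 0.79), and its sign turned with DESeq2's size factors, upper quartiles or library totals in place of TMM, to 0.05, 0.06 and 0.80, and without normal 3, irradiated 1 or irradiated 3, to 1.18, 0.25 and 0.41.

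Muscle genes gave no passing member in the sarcomere lists. The adult and mature sarcomere list was called higher by camera (47 tested, adjusted p = 0.0182, adjusted p = 0.931 with an estimated correlation), while its median log2 was -0.20, its mean -0.22 and 32 members were negative. The median was 0.21 with library totals in place of TMM factors and 2.14 without normal 3, the library in which the list took 17.1% of counts. It was -2.02 without irradiated 1, 0.13 without irradiated 2 and 0.18 without irradiated 3. The call was lost without irradiated 1, normal 1 or normal 2 (camera adjusted p = 0.798, 0.791 and 0.492), and at a mean of at least 50 CPM (0.389). Tnni1 averaged 359 and 241 CPM and Actn2 80.9 and 160 CPM in irradiated and normal constructs, Actn2 turning to a log2 of 1.48 without normal 3. Developmental sarcomere genes had a median log2 of 0.39 (16 tested, camera adjusted p = 0.173). Myog, the transcription factor of myoblast differentiation, averaged 316 ± 199 and 256 ± 106 CPM (log2 0.31 ± 0.49, and -0.27 without irradiated 1), and embryonic myosin heavy chain, Myh3, 219 ± 148 and 173 ± 91.7 CPM (log2 0.34 ± 0.61, and -0.18 without irradiated 3). Neither passed.

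Housekeeping lists were called with medians near 0. Nuclear-encoded genes of the list oxidative phosphorylation, nuclear encoded (39 tested, median log2 0.07, camera adjusted p = 0.0212, adjusted p = 0.916 with an estimated correlation) had no passing member, and Uqcrb averaged 133 and 75.3 CPM in irradiated and normal constructs. This call was lost without normal 1, normal 2 or irradiated 1 (camera adjusted p = 0.407, 0.198 and 0.189), each with a negative median, and without normal 2 there were 5 called lists in place of 8. The ribosomal proteins list (39 tested, median log2 0.04, camera adjusted p = 0.0178, adjusted p = 0.796 with an estimated correlation) had none either, and Rpl4 averaged 517 and 316 CPM. Rps9 went the other way, with a log2 of -0.98 to -0.53 as each library was left out. The ribosomal call was lost without normal 3, irradiated 2 or irradiated 3 (camera adjusted p = 0.0520, 0.0614 and 0.145), with a median of -0.04 without normal 3. At a mean of at least 50 CPM the oxidative phosphorylation and ribosomal calls were lost as well (camera adjusted p = 0.282 and 0.306). Among stress genes, 3 of 33 immediate early and heat shock members fell adjusted over the list alone, including the AP-1 component Jun (log2 -1.48 ± 0.32) and Ier3 above. Of 29 NRF2 antioxidant members, Sod3 fell (log2 -1.96 ± 0.40) and Gstm1 rose (log2 1.67 ± 0.38), and neither list was called by camera, while fry called the immediate early and heat shock list lower (adjusted p = 0.0310).

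Markers of other cell types were tested as lists. The list neural and Schwann markers was called lower (13 tested, 11 negative, median log2 -1.21, camera adjusted p = 0.00527, adjusted p = 0.756 with an estimated correlation). The median was -7.88 without irradiated 1 and between -5.74 and -1.98 without any other library except normal 2 (-1.32), with 14 to 17 members then tested. Adjusted over the list alone 4 fell, Gap43, Nefm, Erbb3 and Nefl, and 3 of these had no count in the irradiated libraries. Without irradiated 1, Nefl and Nefm passed over all genes (edgeR adjusted p = 0.00774 and 0.0345), as did the adipocyte marker Agpat2 (0.0460). Irradiated 1 held all irradiated counts of Nefl, so the call of Nefl without that library rests on their removal. Adjusted over the list alone, 1 member fell in the immune list (Cd14, log2 -4.76 ± 1.08, and -3.75 without normal 1 or -6.29 without irradiated 2) and the adipocyte list (Agpat2, without counts in irradiated constructs), and Phex rose in the osteoblast and cartilage list (log2 2.10 ± 0.59). Endothelial and pericyte markers had no passing member. Across all tested genes the median log2 fold change was -0.21, and -1.31 among the 2995 genes of lowest abundance. With library totals in place of TMM factors the median of all genes shifted by 0.35.

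The remaining lists were not called by camera in irradiated against normal constructs, and fry called nuclear RNAs (adjusted p = 0.0418) and TGF-beta (0.0459) lower. Median log2 was 0.86 for interferon response (19 tested, camera adjusted p = 0.0502), -0.77 for DNA replication, 0.08 for DNA damage repair, 0.06 for matrix proteases, -0.43 for integrins and focal adhesion, -0.59 for myoblast fusion, -0.45 for glycolysis and hypoxia and -0.40 for nuclear RNAs, with no passing member. Medians that turned positive with library totals were those of senescence core markers (-0.32), calcium handling (-0.17), atrophy (-0.18), mitochondrially encoded genes (-0.31), ER stress (-0.18), fibroblast and tendon markers (-0.26) and cholesterol and fatty acid synthesis (-0.02), the last also with DESeq2's size factors or upper quartiles, again with no passing member. The TGF-beta list (-0.40) had 2 members that fell adjusted over the list alone, Inhba and Ccn2, and the myogenic regulator list (-0.09, positive with library totals) had 1, Sdc4. Endothelial and pericyte markers had a median of -0.44. Median, mean and camera direction differed in sign for DNA damage repair, matrix proteases, matrix crosslinking, matrix glycoproteins, myoblast fusion, calcium handling, atrophy, mitochondrially encoded genes, NRF2, cholesterol, adipocyte, osteoblast and fibroblast lists.

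**Figure D3:**
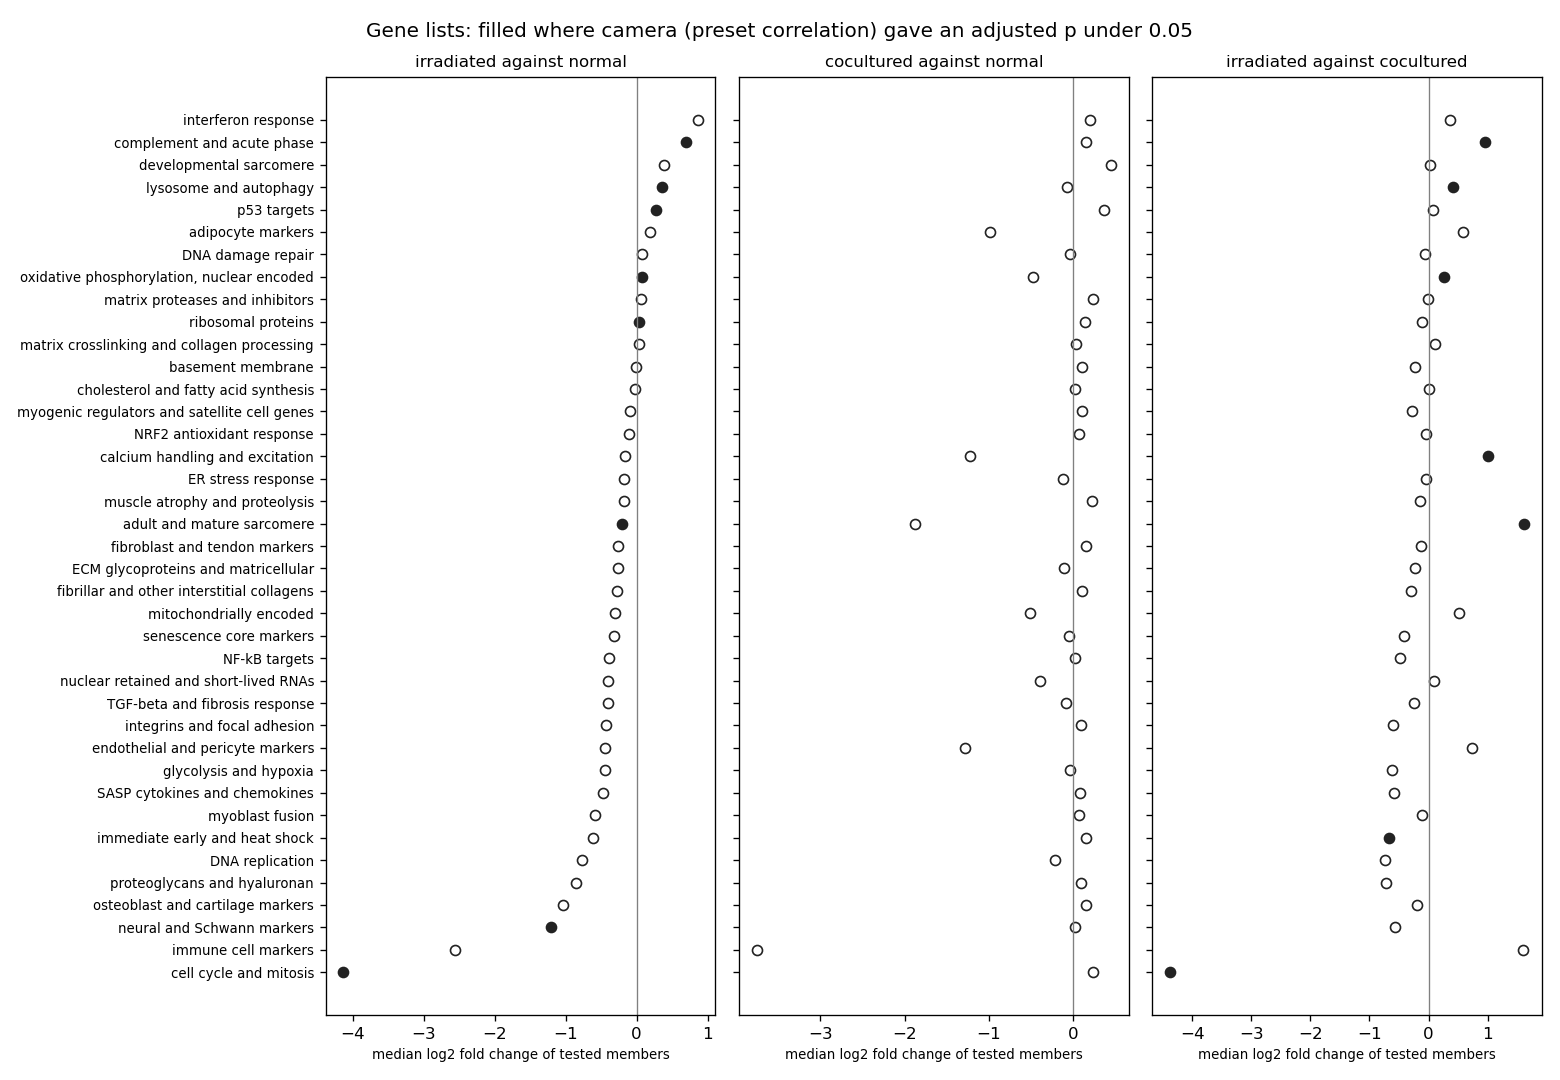
Median log2 fold change of the tested members of each of the 39 gene lists in the 3 comparisons, with genes without counts in a group set to their bound. Filled points mark lists called by camera at the preset correlation, 8, 0 and 7 lists from left to right, and the cell cycle and mitosis list has the lowest median in the left and right panels.

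The second comparison asked whether sharing a dish with an irradiated construct changed a normal one. No gene among 11980 passed in cocultured against normal constructs by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 492 genes, 102 higher and 390 lower, below the 599 expected by chance. limma voom called 0 and DESeq2 138, 14 higher and 124 lower. Cdkn1a averaged 1248 CPM in cocultured and 996 in normal constructs (log2 0.33 ± 0.33), Mdm2 127 and 65.0 CPM (log2 0.97 ± 0.50), Il6 260 and 327 CPM (log2 -0.33 ± 1.19), Ccl2 70.2 and 33.2 CPM (log2 1.08 ± 1.25) and Mki67 52.6 and 29.6 CPM (log2 0.83 ± 1.54), and none of these passed. Il6 turned to 0.06 without normal 1 and to 0.24 with library totals in place of TMM. Myog differed by a log2 of 0.10 ± 0.49, Myh3 by 0.26 ± 0.61, Lmnb1 by 0.71 ± 1.72 and Col1a1 by -0.89 ± 0.79, and the first, second and last of these changed sign without normal 3, to -0.04, -0.01 and 0.29. Myog was also negative without normal 1 (-0.05) or cocultured 1 (-0.17). Of the genes called after irradiation, Fbln7 averaged 41.3 ± 10.5 CPM in cocultured and 10.7 ± 7.45 in normal constructs (log2 1.96 ± 0.53), Col12a1 408 and 806 and Inhba 233 and 459, each with an edgeR adjusted p of 1.

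None of the 39 lists was called in this comparison by camera, by camera with an estimated correlation or by fry. The smallest adjusted p in camera was 0.0502, for ribosomal proteins (29 of 39 positive, median log2 0.14), with an adjusted p = 0.953 with an estimated correlation, and no member of any list passed adjusted over the list alone. The p53 target list had a median log2 of 0.36 (camera adjusted p = 0.226), the SASP list 0.08 (0.577) and the cell cycle and mitosis list 0.23 (0.182). The adult and mature sarcomere list had a median log2 of -1.88 (0.226), and of 0.51 without normal 3, the library in which it took 17.1% of counts (camera adjusted p = 0.0789), and it was called higher, at 0.0371, without both normal 3 and irradiated 1. Leaving out normal 2 gave 3 called lists, cocultured 3 gave 2, and normal 1, each irradiated library or cocultured 1 gave 1. Simulated genes with the estimated spread were recovered in this comparison at 0% of 50 for a 2-fold change, 12% for 4-fold, 16% for 8-fold and 22% for 16-fold, so most changes of these sizes were not detectable at this spread.

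The irradiated and cocultured constructs were also compared directly, which tests the difference between their departures from normal. Nt5e, Rrp1b and Gap43 were without counts in irradiated constructs and averaged 110 ± 28.3, 54.6 ± 21.5 and 54.0 ± 2.25 CPM in cocultured ones, at least 877-fold, 434-fold and 429-fold lower. Here too the bounds cover counting error only. Hspa4l, a heat shock protein of the HSP110 family, fell to 37.9 ± 2.95 from 278 ± 83.5 CPM (SD, n = 3 each; log2 -2.87 ± 0.39). These 4 were the genes called, with edgeR adjusted p-values of 3.39e-04 for Nt5e, 0.0134 for Rrp1b and 0.0144 for Gap43 and Hspa4l. limma voom called 105 and DESeq2 635. In the panel none passed with all 9 libraries: Cdkn1a differed by a log2 of 0.37 ± 0.33, Mdm2 by -0.93 ± 0.50, Lmnb1 by -3.38 ± 1.88, Mki67 by -4.76 ± 1.80, Il6 by -3.43 ± 1.31 and Col1a1 by 0.88 ± 0.79, which was -0.22 without irradiated 2. Without irradiated 1 Mki67 and Lmnb1 were called lower (edgeR adjusted p = 0.0167 and 0.0273), and without irradiated 3 Il6 was (log2 -8.10, 0.00469). Each of these fits leaves out the library that held all or most of the gene's irradiated counts, so they add no support. Ccl2 (-0.23 ± 1.23), Myog (0.20 ± 0.49) and Myh3 (0.08 ± 0.61) changed sign without cocultured 3, to 0.25, -0.06 and -0.30. Ccl2 was also positive without irradiated 1 (0.35) or irradiated 2 (0.29), Myog negative without irradiated 1 (-0.37) or with library totals (-0.11), and Myh3 negative without irradiated 2 or irradiated 3 (-0.44). Fbln7 was at 334 and 41.3 CPM (log2 3.02 ± 0.54, edgeR adjusted p = 0.124). At an unadjusted p under 0.05 there were 1148 genes, 270 higher and 878 lower.

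An edgeR fit of the 6 libraries compared called 0 genes. Nt5e was called with each library left out. Rrp1b was lost without normal 1 (edgeR adjusted p = 0.0616) or normal 3 (0.0543), Gap43 without normal 1 (0.0616), normal 3 (0.0505) or cocultured 3 (0.0611), and Hspa4l without normal 1 (0.0505), normal 3 (0.0505) or cocultured 3 (0.149). The count was 1 without normal 1 or normal 3, 2 without cocultured 3, 97 without irradiated 1, 11 without irradiated 2, 13 without irradiated 3, 8 without cocultured 1, 7 without normal 2 and 21 without both normal 3 and irradiated 1.

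The list cell cycle and mitosis had the lowest list median here too, with all 32 members negative, a median log2 of -4.89 (-4.38 with genes without counts at their bound) and 7 that fell adjusted over the list alone. Without irradiated 1, 2 or 3 the fitted median was -8.70, -7.04 and -6.57. The list was called lower (camera adjusted p = 4.17e-13, adjusted p = 0.380 with an estimated correlation). Of the SASP list 4 of 30 members fell adjusted over the list alone, and the list was not called (camera adjusted p = 0.0760), except lower by fry (adjusted p = 0.0343). The lists called higher were adult and mature sarcomere (median log2 1.62, camera adjusted p = 1.77e-05), calcium handling and excitation (1.01, 0.00392), oxidative phosphorylation, nuclear encoded (0.26, 0.0299), lysosome and autophagy (0.41, 0.00171) and complement and acute phase (0.95, 0.0333). Immediate early and heat shock genes were called lower (-0.67, 0.0333). With an estimated correlation these 6 calls were lost, with an adjusted p = 0.380 for the lysosome, complement and immediate early lists and an adjusted p = 0.842 for the sarcomere, calcium and oxidative phosphorylation lists. At a mean of at least 50 CPM the lysosome (camera adjusted p = 0.0802), calcium (0.0591) and complement (0.856) calls were lost, while 3 of the 7 lists were called there too.

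Several of these calls were lost with 1 library left out, and the number of called lists was 2 without irradiated 1, 4 without irradiated 2 and 3 without cocultured 2. Without irradiated 1, the library with 13.4% of counts on the adult and mature sarcomere list, that list was lost at a camera adjusted p of 0.150, calcium handling and excitation at 0.381, and oxidative phosphorylation, nuclear encoded, at 0.373, with complement and acute phase and immediate early and heat shock at 0.0591. The medians were then 0.17 for the adult and mature sarcomere list, 0.09 for calcium handling, -0.06 for oxidative phosphorylation and 0.29 for complement. Without irradiated 2 oxidative phosphorylation (0.0925), lysosome and autophagy (0.139) and complement (0.240) were lost, and without irradiated 3 complement (0.0804). Without cocultured 1 oxidative phosphorylation and complement were lost (0.130 each), without cocultured 2 calcium handling and complement (0.0776 each), oxidative phosphorylation (0.101) and immediate early genes (0.0514), without cocultured 3 complement (0.0646) and immediate early genes (0.230), and without normal 1 complement (0.0502).

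With all 9 libraries in edgeR, no gene was called in both comparisons against normal constructs. In the edgeR fit omitting normal 3 and irradiated 1, Gm26917 was called lower in both. Its log2 was -2.77 in irradiated (adjusted p = 0.0176) and -3.18 in cocultured constructs (0.00528). Without irradiated 1, the sets split by Gm26917 share and TMM factor are normal against all others, so a difference in preparation is not excluded. Over the tested genes, the log2 fold changes of the irradiated and cocultured effects correlated at 0.280 across genes, which are not independent replicates, with a covariance of 1.60. In 20 simulations of unchanged groups sharing the normal libraries, the correlation averaged 0.511 (0.483 to 0.529) and the covariance 2.14 (1.99 to 2.31), both above the observed values. The simulations gave each gene the same dispersion in all groups. Within-group Spearman correlations were 0.634 to 0.641 in irradiated but 0.709 to 0.826 in normal libraries. The simulated controls may thus vary too much, so the values that shared controls alone would give are not settled. DESeq2 called 52 genes in both, 11 higher and 41 lower, where independent lists would share 0.124 and 5.17. The 3 normal libraries were too few to split, so part of that excess may come from the shared controls.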

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

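The abundance floor of 50 CPM, the omission of both normal 3 and irradiated 1, and voom with library weights were chosen after the data were seen, and the other alternatives before. In irradiated against normal 7 genes were called, and 7 also with DESeq2's size factors, upper quartiles, a stricter filter, no mitochondrial genes or a log2 fold minimum of 1. The count was 667 with DESeq2, 25 with limma voom, 130 with no filter (18619 genes tested), 0 with only the 2 groups compared, 24 with at least 50 CPM, 20 omitting both libraries, 15 with library weights (12 higher and 3 lower), and 6 to 147 with each library left out. With library weights only Fbln7 of the 7 was called, and the other 6 had adjusted p-values of 0.0887 to 0.478. In cocultured against normal the count of 0 became 138 with DESeq2, 52 with no filter, and 1 omitting both libraries or with library weights. It stayed 0 with limma voom and in every edgeR fit with 1 library left out, with 492 genes at an unadjusted p under 0.05 in edgeR. In irradiated against cocultured the count of 4 became 9 with library totals, 635 with DESeq2, 105 with limma voom, 153 with no filter, 0 with only the 2 groups compared or with library weights, 2 with at least 50 CPM, 21 omitting both libraries, 1 at an adjusted p under 0.01, and 1 to 97 with each library left out. Genes shared by both comparisons against normal numbered 52 with DESeq2 and 0 with the replicate block, a log2 fold minimum of 1 or each library left out. Omitting both libraries, Gm26917 was called lower in both comparisons, but these are the libraries in which its share overlapped between groups. Fewer genes are tested under the floor and fewer samples enter the smaller fits; otherwise the cause was not tested.

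The 8 lists called in irradiated against normal became 0 with an estimated correlation or with at least 50 CPM, and 5 to 8 with each library left out; fry called 8, all lower, of which 2 (cell cycle and neural) were among them, the others being SASP, basement membrane, TGF-beta, immediate early, immune and nuclear RNA lists. In cocultured against normal 0 lists became 1 with at least 50 CPM, 4 omitting both libraries and 0 to 3 with each library left out. In irradiated against cocultured 7 lists became 0 with an estimated correlation, 4 with fry (cell cycle, immediate early, SASP and basement membrane, all lower) and 2 to 7 with each library left out, and the complement and acute phase list turned downward with at least 50 CPM (camera adjusted p = 0.856).

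Changes of sign were among genes that did not pass over all genes tested. In irradiated against normal Ccl2 was -1.17 with limma voom and -1.44 with library weights, Myog -0.0569 with limma voom and -0.41 omitting both libraries, and Myh3 -0.0388 with library weights. Col1a1 was 0.0520 with DESeq2's size factors, 0.0591 with upper quartiles, 0.80 with library totals, 0.0539 with DESeq2, 0.40 with limma voom, 1.44 omitting both libraries and 0.44 with library weights. With each library left out Mdm2 ranged from -0.20 to 0.33, Ccl2 from -2.82 to 1.43, Myog from -0.27 to 0.70, Myh3 from -0.18 to 0.84, Col1a1 from -1.11 to 1.18, Myoz3 from -9.07 to 0.97 and Actn2 from -3.48 to 1.48. In cocultured against normal Il6 was 0.24 with library totals, Myog -0.0426, Myh3 -0.0163 and Col1a1 0.29 omitting both libraries, and Col1a1 0.19 with library weights. With each library left out Il6 ranged from -0.67 to 0.0571, Myog from -0.17 to 0.50, Myh3 from -0.0150 to 0.77 and Col1a1 from -1.33 to 0.29. In irradiated against cocultured Ccl2 was 0.37 omitting both libraries, Myh3 -0.32 with library weights, and Myog -0.11 with library totals, -0.17 with limma voom, -0.37 omitting both libraries and -0.11 with library weights. With each library left out Ccl2 ranged from -3.90 to 0.35, Myog from -0.37 to 0.57, Myh3 from -0.44 to 0.52 and Col1a1 from -0.22 to 1.30. The cause of these changes was not tested.

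No pairing of samples by replicate number was seen: the deviations of same-numbered samples correlated at -0.0710 to 0.0537, with 0 of 9 pairs over 0.1, and 7 of 18 best partners had a sample's own number. With 3 libraries per group this cannot exclude a pairing. With the replicate block 23, 0 and 12 genes were called in the 3 comparisons, 9, 0 and 6 lists. In irradiated against cocultured the immediate early and heat shock list was then lost (camera adjusted p = 0.0560). The 23 included Top2a (adjusted p = 0.0311), Il1a (0.0189), Ptgs2 (0.00504) and Igfbp2 (0.0380), and Ccl2 was -1.27 in irradiated against normal. Depth limits what a count of 0 in a library allows, up to 0.282 (irradiated 2) to 0.821 normalised CPM (normal 3) at a floor of 3 counts per library, for counting error only. Shares of genes without counts did not follow library totals: among genes of 20 to 50 CPM on average in normal and cocultured libraries it was 20.8% in irradiated 2, which had the highest total (8290468), and 0.101% in normal 2, which had the lowest (4840993).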

Other observations

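All tests of the 3 patterns below were chosen after the values were seen. The counts over other splits of the samples were planned. An abundance floor of 50 CPM on average, also chosen after seeing the data, left 3196 genes, of which 24 were called in irradiated against normal constructs, 11 higher and 13 lower. Besides genes already described, these included the selenium carrier Selenop (log2 2.77 ± 0.49), the matrix-associated Aebp1 (1.56 ± 0.29) and Ly6e (1.89 ± 0.31), which were higher, and the receptor kinase Axl (-1.87 ± 0.29) and the BMP antagonist Grem1 (-2.09 ± 0.34), which were lower. These genes were named after their values were seen.

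Adult sarcomere genes were high in normal 3 and irradiated 1, libraries of different groups, with median log2 excesses of 4.09 and 3.26 over the other 2 libraries of the group (47 members, all of which exceed 1 CPM on average over the other 7 libraries). A higher number of myotubes of the same stage would raise developmental sarcomere genes too, and their median of -0.71 in normal 3 (bootstrap interval -1.34 to -0.05, 14 members) argues against it there, while 0.13 in irradiated 1 (-1.18 to 2.40) leaves it open. Whether irradiated 1 is a mislabelled unirradiated library was examined by its position from normal (0) to irradiated 2 and irradiated 3 (1). Its median was 0.213 (interval over genes 0.147 to 0.298) over the 147 genes called without it, against 0.0318 to 0.0622 in the cocultured libraries. This is nearer to normal than to the other irradiated libraries, and 15 of the 147 genes had no count in irradiated 1. A second version, added after that value was seen, left out normal 3 too and gave 0.474 (0.276 to 0.584) over 20 genes, against 0.0763 in normal 3, although these intervals do not cover the spread between libraries. Both positions lay above those of the unirradiated libraries, which argues against a mislabel but, resting on a single library, does not exclude it. RNA from mature muscle, for example from the tissue the matrix was made of, may have been present in both libraries. The log2 ratio of their excesses, taken over the 43 of 47 members raised in both, varied with an SD of 0.818. This lies between the bounds set for and against mature muscle RNA, and the members not raised in both did not enter it. That source thus stays open, as does further maturation of the myotubes, which was not tested.

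In irradiated constructs 944 tested genes had no count in any of the 3 libraries, where independent loss within abundance classes gives 762 (highest of 1000 draws 845). The cocultured libraries exceeded their own expectation by more, 414 against 186, so a random loss of transcripts in libraries of low complexity cannot be told apart from a change in expression for these genes as a whole. In the cell cycle and mitosis list 11 of 32 members were without counts. In 10000 random lists matched on abundance the median was 2 and the maximum 7 (share 1e-04, the smallest these draws can give). This is more than loss at random with respect to gene function gave in the draws. The list was chosen after its values in these libraries were seen, and the draws take members as independent, so the share cannot exclude such loss. A lower expression of cell division genes after irradiation is a candidate explanation for that list.

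Of the SASP list, 10 members fell in irradiated constructs when adjusted over the list alone. Of these, 5 were at 0 in 1 or more irradiated libraries and 5 had counts in all 3, so loss of low-abundance transcripts is neither excluded nor shown and may account for part of them. The median log2 of all 10 was -3.34 with all libraries and -3.31 without normal 3 and irradiated 1, so their fall did not rest on irradiated 1. The 10 were picked because they fell in these same libraries, so this is no independent test of dilution by mature muscle RNA there. An effect of irradiation remains a hypothesis, and other technical causes were not tested.

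The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The other group's 3 libraries stayed in each fit, while a fit of the 6 libraries alone called 0 genes in irradiated against normal and in irradiated against cocultured constructs. In irradiated against normal the real split gave 7 genes and the highest of the others 0, so that 1 split gave as many as the real one, itself included. In irradiated against cocultured the values were 4 and 0, again with 1 split. In cocultured against normal both were 0, and all 10 splits gave as many.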
